A study of Homo sapiens with 10 samples.

How the data were processed

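The series measured RNA of MiaPaCa-2 cells on 10 Affymetrix U133 Plus 2.0 arrays, 8 treated and 2 control. Values were log2 intensities made by the authors with RMA, per the submitters' processing notes, which give no version. Their distributions over arrays were checked and lay on a log2 scale. The table of 54675 probe sets was used for every test, and a filtered table of 7622 probe sets (13.9%) that was also deposited served as an alternative. Its log2 values equalled those of the full table within 5e-09. The rule behind the filtering was not given in the sources used here. Kept probe sets had a median SD over arrays of 0.333 and left-out ones 0.160, but 15827 left-out probe sets had an SD above the lowest kept.

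Of the probe sets, 41097 carried 1 gene symbol in the platform annotation, 1801 several and 11777 none. Only those with 1 symbol were used for genes, which gave 19775 genes, 10523 of them with several probe sets. The entrez identifiers of 41043 probe sets were found in the current RefSeq gene table, and 0 symbols needed an update. For each gene the probe set with the highest mean over the 10 arrays was kept, and genes with a mean at or above the 40th percentile (log2 5.79) were tested, 11865 in all. Probe sets without a single symbol were tested apart, under the same filter.

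Groups were taken from the labels. The treated hours 1 to 3 and 4 to 7 were taken as windows of 3 and 4 arrays, so the spread within a window includes change with time. In limma 3.58.1 under R 4.3.3, lmFit and eBayes gave two-sided tests of 5 comparisons: treated against control over all 10 arrays (8 residual degrees of freedom), hours 1 to 3 against control, hours 4 to 7 against control and the windows against each other in a fit of 9 arrays without the 24 h treated array (6 degrees of freedom), and the slope on hour over the 7 arrays from 1 to 7 h (5 degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the genes of each comparison with a threshold of 0.05. The 24 h treated array against the 24 h control, the controls against each other and each treated array against each control were single-array differences, described by size, with genes counted at an absolute log2 difference of 1 or more. A quadratic in hour was tested by limma's F test of both terms and by the test of its quadratic term alone. The arrays' number limits the precision.

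The 34 gene lists were written before the values were seen and tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 34 lists. For single-array differences the list median was placed among 10000 random lists matched on mean level in 20 bins. Genes named in the text follow a rule also set beforehand. It took, per tested comparison, the 10 largest rises and 10 largest falls past the threshold (or the next by unadjusted p up to 5 where fewer passed), the 10 largest differences each way for the 24 h pair and the control pair, and the 4 members with the smallest p of each list described.

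The fits were tested on simulated data with 200 changed genes among 11865, 100 at each of 2 sizes. Normal noise was drawn independently for each gene and array, without drift over time or correlation between genes. The shares and false calls below hold for such noise and do not measure how the fits performed on these arrays. At a log2 size of 1 the test of treated against control recovered 83%, hours 1 to 3 against control 96%, hours 4 to 7 against control 98% and the windows against each other 97%, with 7, 7, 9 and 12 false calls. At a size of 2 the shares were 100%, 100%, 99% and 100%. A slope of 0.2 per hour was recovered in 99% and one of 0.4 in 100%, with 5 false calls.

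Alternatives were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, cyclic loess scaling, the filtered table, an intensity trend with a robust prior, leaving out each array in turn, each control alone, a term for late harvest, the 24 h treated array kept as a lone group, other forms of the trend, other references and other size thresholds. With each probe set on its own, the counts are of probe sets, including those without a single symbol. Where a fit was left with 1 control, that array was assumed to vary like the treated ones. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading tables and plotting.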

Results

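MiaPaCa-2 cells, a human pancreatic tumour line, were profiled on 10 Affymetrix U133 Plus 2.0 arrays, 8 after exposure to supernatant of stimulated pancreatic stellate cells and 2 without it. Stellate cells are the fibroblast-like cells that deposit the matrix around pancreatic tumours, and here they had first been stimulated with supernatant pooled from tumour cell lines. The treated arrays covered 1, 2, 3, 4, 5, 6, 7 and 24 h of exposure and the controls 0 and 24 h, with 1 array at each time, and the question was how expression in tumour cells answers to stellate cell products over time. Nothing in the sources states that the arrays came from separate cultures, so the p-values measure only the spread between these samples. The groups, windows of hours, gene lists and thresholds were set before the data were examined. Errors beside log2 changes are standard errors of the limma fit, and single-array differences have none.

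The controls differed from each other in genes of cell division and of amino acid stress. KLHDC7B, which encodes a Kelch and F-box protein of unsettled function, was 3.81 higher on the log2 scale in the 24 h control than in the 0 h control. GDF15, a stress-induced cytokine, was 2.91 higher, and NUPR1, a stress-induced chromatin protein, was 2.78 higher. GINS2, a part of the replicative helicase, differed by -2.33 and KIF20A, a kinesin of cell division, by -2.02. In total 276 of 11865 genes were apart by 2-fold or more, 100 higher and 176 lower in the 24 h control. Among 26 targets of ATF4, the transcription factor of the amino acid response, 20 were higher by 1 log2 unit or more and the median difference was 1.42. The median of 33 G1/S and replication genes was -1.15 and that of 36 G2/M and mitosis genes -0.99. Against 10000 random lists matched on mean level, the ATF4 median lay at percentile 100 and the other medians at percentile 0. These are differences between single arrays and carry no test.

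NFKBIZ, which encodes an atypical regulator of NF-kB, rose by 2.81 ± 0.22 in the 8 treated arrays against the 2 controls (limma adjusted p = 0.000608). TNFAIP3 and NFKBIA, feedback inhibitors of NF-kB, rose by 1.81 ± 0.25 (adjusted p = 0.0288) and 1.37 ± 0.17 (adjusted p = 0.0178). CXCL1 and CXCL2, chemokines that attract neutrophils, rose by 1.32 ± 0.14 and 1.51 ± 0.19, and IER3, an early-response gene acting on cell survival, rose by 1.17 ± 0.16. For each of these 6 genes all 8 treated arrays lay above both controls, and at 24 h NFKBIZ was still 2.06 above the 0 h control and 2.01 above the 24 h control. No gene of the 11865 fell past the threshold with all arrays, the 40th percentile filter and 1 probe set per gene. USP20, a deubiquitinating enzyme, came nearest at -0.54 ± 0.08 (adjusted p = 0.0606). An unadjusted p under 0.05 was reached by 1615 genes. Among 23 NF-kB targets the median change was 0.64, with 3 past the threshold over all genes and 13 adjusted over the list alone (camera adjusted p = 2.43e-13, and adjusted p = 0.0826 with an estimated correlation). The median of 14 chemokines and cytokines was 0.92, with 2 past the threshold and 9 adjusted over the list alone (camera adjusted p = 3.08e-08, and adjusted p = 0.126 with an estimated correlation). Falls appeared when an array was left out, and the count of 6 was 115 without the 24 h treated array, 56 of them lower, 41 without the 1 h array, 24 of them lower, 2 without the 2, 3, 4 or 6 h array and 1 without the 0 h control, and NFKBIZ alone passed in every such fit. Without the 0 h control the adjusted p was 0.397 for TNFAIP3, 0.374 for IER3, 0.315 for NFKBIA and CXCL2 and 0.158 for CXCL1. Calls of single genes also ended without the 24 h control (TNFAIP3, 0.0727; NFKBIA, 0.07; CXCL1, 0.0576), the 5 h array (TNFAIP3, 0.082; IER3, 0.0768) and the 7 h array (TNFAIP3, 0.0595).

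MT1M, a metallothionein that binds zinc and copper, rose by 5.99 ± 0.51 in the 3 arrays of hours 1 to 3 against the 2 controls (limma adjusted p = 0.000834). It lay 6.46 above the 0 h control and 5.52 above the 24 h control, whose levels of 4.12 and 5.06 were under the level of 5.79 used as the filter on mean expression. MAP3K8, a kinase that activates the ERK pathway, rose by 4.17 ± 0.41, and CXCL3, a chemokine, rose by 2.92 ± 0.24. EGR3, a transcription factor of the first wave after stimulation, rose by 3.10 ± 0.37 (adjusted p = 0.00415, and 0.0525 without the 0 h control). MTRFR, a mitochondrial translation release factor, fell by 1.09 ± 0.12, and IGFBP4, which binds insulin-like growth factors, fell by 1.12 ± 0.19 (adjusted p = 0.0229, and 0.106 without the 2 h array). Without the 0 h control the change of IGFBP4 was only -0.73 and its call ended. For each of these 6 genes the 3 arrays lay beyond both controls. SLC30A1, a zinc exporter, rose by 3.72 ± 0.76 with 2 of its 3 probe sets going the same way, and HMOX1, haem oxygenase, rose by 3.71 ± 0.71. Without the 0 h control SLC30A1 stood at 2.82 (adjusted p = 0.246) and HMOX1 at 3.10 (adjusted p = 0.217). The call of SLC30A1 also ended without the 1, 2, 3, 5 or 6 h array (adjusted p from 0.0509 to 0.15) and that of HMOX1 without the 2, 3, 5 or 6 h array (from 0.0602 to 0.136).

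In the first 3 h, 233 of 11865 genes passed the threshold, 100 of them higher and 133 lower, and 44 and 12 of these changed by 2-fold or more. After cyclic loess scaling the split was 169 higher and 124 lower, so the prevailing direction turned with the scaling. It also turned with the control, with 574 higher and 1249 lower against the 0 h control alone and 21 higher and 2 lower against the 24 h control alone. Of 9 metallothionein and zinc transport genes, 8 rose, both over all genes and adjusted over the list alone, with a median of 1.15 (camera adjusted p = 2.41e-13, and adjusted p = 0.168 with an estimated correlation). Of 26 immediate-early genes, which are switched on without new protein synthesis, 7 rose over all genes and 17 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.13e-12, and adjusted p = 0.177 with an estimated correlation). Their median was 1.02 against the 0 h control alone and 0.29 against the 24 h control alone. Of 14 chemokines and cytokines, 5 rose over all genes and 9 adjusted over the list alone, with a median of 1.05 (camera adjusted p = 1.91e-09, and adjusted p = 0.168 with an estimated correlation). The median of 36 G2/M genes was -0.55 with 0 past the threshold in limma, over all genes and adjusted over the list alone (camera adjusted p = 2.78e-07, and adjusted p = 0.637 with an estimated correlation), and against the 24 h control alone it was -0.06 (adjusted p = 0.677). The median of 33 G1/S genes was -0.49, also with 0 past the threshold over all genes and adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.758 with an estimated correlation), and it was -1.05 against the 0 h control alone and 0.16 against the 24 h control alone. The count of 233 was 1823 without the 24 h control, 23 without the 0 h control, 509 without the 1 h array, 31 without the 2 h array (28 higher and 3 lower), 90 without the 5 h array and 93 without the 6 h array.

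NFKBIZ and MT1M stayed high at hours 4 to 7, while TXNIP, DDIT4 and ID3 fell. NFKBIZ stood 2.95 ± 0.11 above the controls in these 4 arrays (limma adjusted p = 1.53e-06) and MT1M 6.94 ± 0.48 (adjusted p = 0.000314). GBP3, a GTPase induced by cytokines, rose by 2.68 ± 0.32, and CXCL6, a chemokine, rose by 2.75 ± 0.47. TXNIP, which curbs glucose uptake and binds thioredoxin, fell by 2.37 ± 0.37, and DDIT4, an inhibitor of mTORC1, fell by 2.02 ± 0.32. ID3, an inhibitor of basic helix-loop-helix factors, fell by 1.93 ± 0.35, and its 4 to 7 h mean lay -2.73 from the 0 h control and -1.13 from the 24 h control. CCNE2, cyclin E2, which drives entry into S phase, rose by 2.57 ± 0.50 (adjusted p = 0.0133), and its distance was 1.72 from the 0 h control and 3.42 from the 24 h control, with adjusted p = 0.0595 without the 24 h control. For all 8 genes the 4 arrays lay beyond both controls.

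At hours 4 to 7, 1636 genes passed the threshold, 902 higher and 734 lower, and 98 and 61 of these changed by 2-fold or more. The prevailing direction turned with the control, with 664 higher and 825 lower against the 0 h control alone and 741 higher and 394 lower against the 24 h control alone. Of 9 metallothionein and zinc transport genes, 7 rose, both over all genes and adjusted over the list alone, with a median of 1.32 (camera adjusted p = 2.58e-09, and adjusted p = 0.429 with an estimated correlation). Of 23 NF-kB targets, 15 rose over all genes and 16 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 8.42e-11, and adjusted p = 0.196 with an estimated correlation). Of 30 ribosome biogenesis and MYC targets, 8 rose over all genes and 15 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 2.2e-05, and adjusted p = 0.429 with an estimated correlation). Of 21 FOXO and growth factor withdrawal genes, 8 fell over all genes and 11 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 4.41e-05, and adjusted p = 0.429 with an estimated correlation). The median of 15 heat shock genes was 0.33, with 5 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.492 with an estimated correlation). Against the 0 h control it was smaller, from 0.123 to 0.291 in the single arrays of these hours. Of 26 ATF4 targets, 8 fell, both over all genes and adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.00372, and adjusted p = 0.678 with an estimated correlation), but the median was 0.21 against the 0 h control alone and -1.01 against the 24 h control alone. The median of 33 G1/S genes was 0.57, with 4 higher, both over all genes and adjusted over the list alone (camera adjusted p = 4.41e-05, and adjusted p = 0.678 with an estimated correlation), and it was 0.02 against the 0 h control alone and 1.10 against the 24 h control alone. The median of 36 G2/M genes was -0.39, -0.82 against the 0 h control alone and 0.14 against the 24 h control alone. The count of 1636 was 858 without the 5 h array, 740 without the 6 h array and 999 without the 7 h array.

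Between the windows, which is a contrast of treated arrays alone, most DNA replication genes measured rose. ORC1, the large subunit of the origin recognition complex, rose by 2.55 ± 0.39 from hours 1 to 3 to hours 4 to 7 (limma adjusted p = 0.00894), CCNE2 by 2.54 ± 0.44 and CDC6, which loads the replicative helicase, by 1.92 ± 0.35. ARRDC3, an arrestin repressed by insulin signalling, fell by 1.76 ± 0.17 (adjusted p = 0.00821), and TRIB3, a pseudokinase of the amino acid response, fell by 2.03 ± 0.41 (adjusted p = 0.0154). EGR3 fell by 1.64 ± 0.31 from its early height. Of 33 G1/S genes, 24 rose over all genes and 30 adjusted over the list alone, all 33 were higher and the median was 1.03 (camera adjusted p = 3.26e-10, and adjusted p = 0.605 with an estimated correlation). Of 26 ATF4 targets, 4 fell over all genes and 11 adjusted over the list alone, with a median of -0.64 (camera adjusted p = 3.33e-07, and adjusted p = 0.644 with an estimated correlation). In all 2064 genes passed, 1449 higher and 615 lower, and after cyclic loess scaling 1137 were higher and 1050 lower. Without the 2 h array 3 genes passed, and the adjusted p was 0.0569 for ORC1, 0.0666 for CCNE2, 0.0701 for CDC6, 0.0646 for EGR3 and 0.0766 for TRIB3, with TRIB3 also at 0.0539 without the 1 h array and 0.0511 without the 6 h array. The count was 620 without the 1 h array, 528 without the 5 h array, 404 without the 6 h array and 866 without the 7 h array.

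Over the hours, fitted slopes were positive for replication genes and negative for amino acid response genes. From 1 to 7 h ORC1 rose by 0.66 ± 0.05 log2 units per hour over the 7 arrays (limma adjusted p = 0.000503) and CCNE2 by 0.64 ± 0.08, while TRIB3 fell by 0.53 ± 0.05 (adjusted p = 0.000519). CCN2, a matricellular protein and target of YAP, fell by 0.49 ± 0.02 per hour, and SLC7A11, the cystine transporter, fell by 0.50 ± 0.06. Of 33 G1/S genes, 31 rose over all genes and 32 adjusted over the list alone, with a median slope of 0.29 (camera adjusted p = 6.99e-21, and adjusted p = 0.253 with an estimated correlation), although their median did not grow from 1 to 2 h. It was 0.06 at 1 h, 0.02 at 2 h and 1.48 at 7 h against the 24 h control, and -1.12, -1.29 and 0.34 against the 0 h control. Of 26 ATF4 targets, 21 fell over all genes and 24 adjusted over the list alone, with a median slope of -0.17 (camera adjusted p = 1.04e-15, and adjusted p = 0.0846 with an estimated correlation). Of 26 immediate-early genes, 16 fell over all genes and 19 adjusted over the list alone, with a median slope of -0.13 (camera adjusted p = 3.88e-09, and adjusted p = 0.0856 with an estimated correlation). Of 13 circadian clock genes, 7 fell over all genes and 9 adjusted over the list alone, with a median slope of -0.07 (camera adjusted p = 0.000252, and adjusted p = 0.0856 with an estimated correlation). In total 3170 genes passed, 1969 rising and 1201 falling, and 1611 without the 6 h array. After cyclic loess scaling 1882 rose and 1639 fell. With the 0 h control added as hour 0 the count was 932, 446 rising and 486 falling, so the prevailing direction turned, and the calls of ORC1 (0.36 per hour, adjusted p = 0.16), CCN2 (-0.31, adjusted p = 0.0504) and SLC7A11 (-0.20, adjusted p = 0.459) ended.

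**Figure D1:**
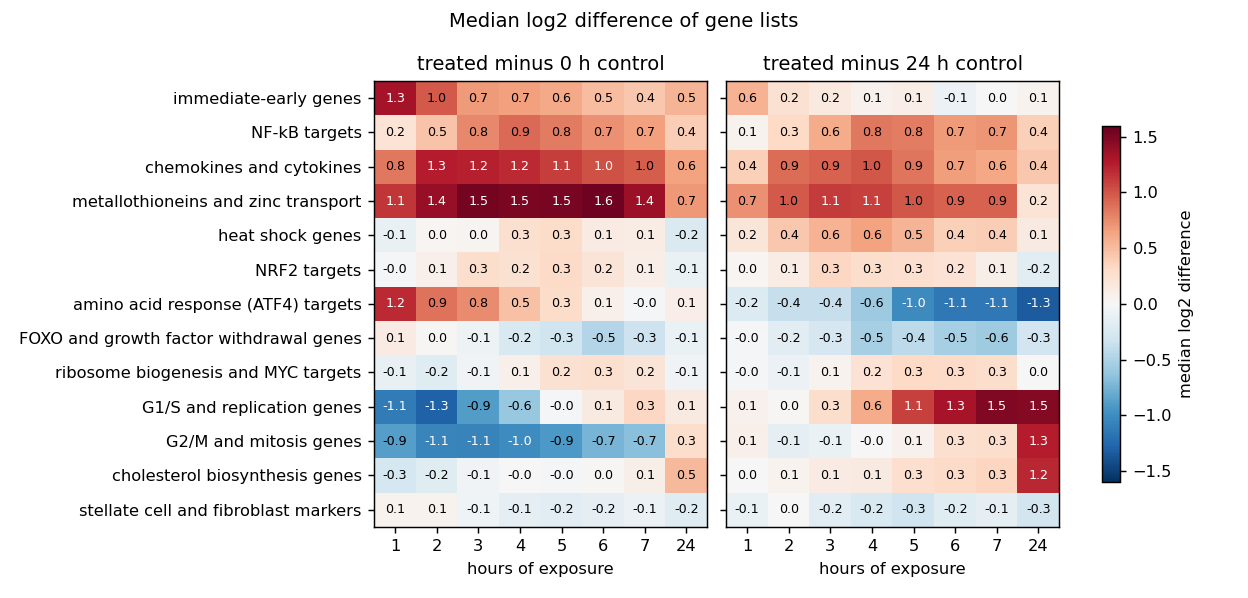
Median log2 difference of 13 gene lists at each hour of exposure (columns, hours), treated minus the 0 h control (left) and minus the 24 h control (right), 1 array per column. The G1/S median reached 1.48 at 7 h against the 24 h control, where the ATF4 median was -1.14, and against the 0 h control they were 0.34 and -0.03.

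HMOX1 rose and then fell part of the way back within the 7 h. It peaked at 3 h, 1.33 above the higher of its 1 h and 7 h levels, and its quadratic term in hour passed (limma adjusted p = 0.00658). At hours 4 to 7 it was still 2.80 ± 0.68 above the controls (adjusted p = 0.0254), with all 4 arrays above both, and its call there ended without the 0 h control (adjusted p = 0.13), the 5 h array (0.0611) or the 6 h array (0.0543). HSPA6, an inducible member of the HSP70 family, also peaked at 3 h, 2.36 above the higher end, and CSF1, the macrophage growth factor, peaked there 1.29 above it, but their quadratic terms did not pass (adjusted p = 0.229 and 0.104). Linear and quadratic terms together passed the F test for 3360 genes, which a linear trend alone can bring about. Of these, 25 had a peak between 2 and 6 h that lay 2-fold or more above both ends, and the quadratic term itself passed for 4 of the 25 and for 32 of all genes. The test of the quadratic term, the peaks and CSF1 were chosen after the values were seen.

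At 24 h the treated array differed from the 24 h control in cell division, sterol and amino acid stress genes, among others. HMGCS1 and MSMO1, enzymes of cholesterol synthesis, were 2.44 and 2.31 higher, and KIF20A was 2.17 higher. MT1M was 2.62 higher, 3.57 against the 0 h control. KLHDC7B differed by -3.25, GDF15 by -2.87 and NUPR1 by -2.70, but against the 0 h control they were higher by 0.57, 0.04 and 0.08. The G1/S median was 1.47 with 24 of 33 genes higher by 1 or more, the G2/M median 1.25 with 28 of 36, and the cholesterol biosynthesis median 1.21 with 12 of 20, each at percentile 100 of 10000 random matched lists. Against the 0 h control these medians were 0.14, 0.28 and 0.52. The ATF4 median was -1.33, with 20 of 26 genes lower by 1 or more and percentile 0, and 0.11 against the 0 h control. In all 387 genes were apart by 2-fold or more from the 24 h control, 266 higher and 121 lower, and 93 from the 0 h control. With 1 array on each side no p-value is given.

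From 2 to 7 h the number of genes apart from the 0 h control fell while that from the 24 h control grew. Against the 0 h control, 388 genes were apart by 2-fold or more at 1 h, 546 at 2 h, 483 at 3 h, 415 at 4 h, 308 at 5 h, 299 at 6 h, 275 at 7 h and 93 at 24 h. Against the 24 h control the counts were 63, 143, 176, 245, 305, 360, 393 and 387 at the same hours. CLGN, a testis-enriched chaperone, and BEX2, a regulator of apoptosis, were near the 24 h control early and near the 0 h control at 24 h. At hours 1 to 3 they lay 2.81 and 2.83 above the 0 h control and -0.0027 and 0.14 from the 24 h control, and at 24 h the treated array lay 0.04 above the 0 h control for both. Both were named for large differences in the control pair and in the 24 h pair. That choice favours their place at 24 h, so they illustrate the pattern and do not test it.

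**Figure D2:**
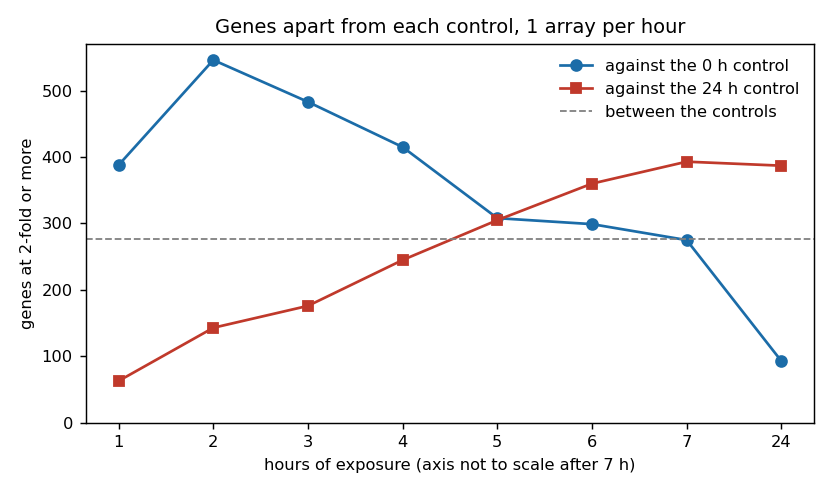
Number of genes of the 11865 tested that were apart by 2-fold or more from the 0 h control (circles) and from the 24 h control (squares), against hours of exposure, 1 array per point. The dashed line marks the 276 genes apart between the controls. The counts at 1 h were 388 and 63 and those at 24 h were 93 and 387.

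**Figure D3:**
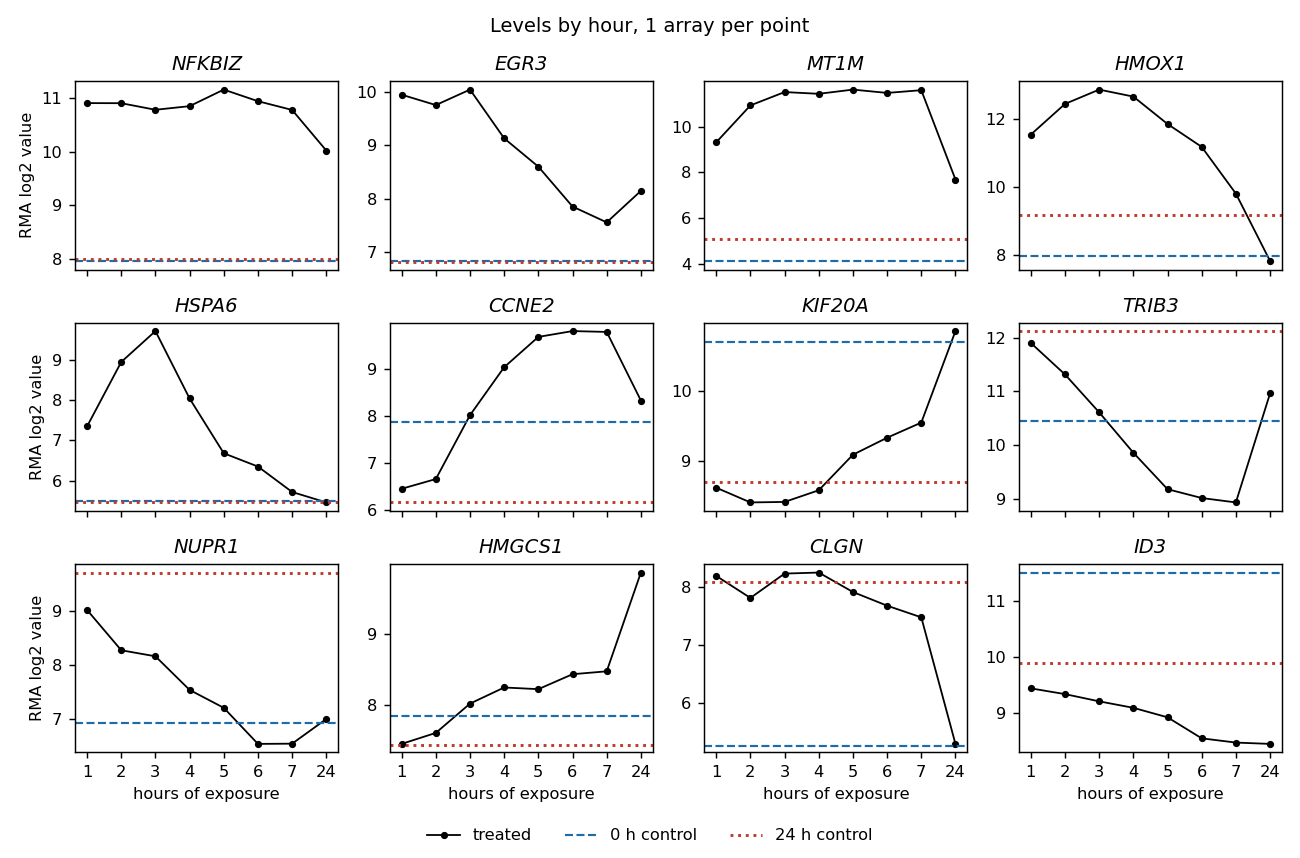
RMA log2 values of 12 genes (vertical axes) against hours of exposure, 1 array per point, with the 0 h control (dashed) and the 24 h control (dotted) as lines. NFKBIZ stayed above both controls at every hour, while CLGN was near the 24 h control up to 7 h and near the 0 h control at 24 h.

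No stellate cell or fibroblast marker rose past the threshold over all genes in the treated arrays. Their median over 18 tested genes was -0.12 in treated against control arrays, with 0 past the threshold over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.0225, and adjusted p = 0.596 with an estimated correlation). At hours 1 to 3 it was -0.04, with 0 past the threshold over all genes and 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.672, and adjusted p = 0.881 with an estimated correlation). At hours 4 to 7 it was -0.19, with 5 lower over all genes, 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.429 with an estimated correlation). The ACTB probe sets showed a 3-prime excess over the 5-prime end of 0.652 at 1 h, 0.588 at 2 h, 0.438 at 3 h, 0.432 at 4 h, 0.394 at 5 h, 0.362 at 6 h, 0.502 at 7 h and 0.328 at 24 h, against 0.289 and 0.290 in the controls. This measure of RNA integrity thus moved with the groups, and it fell at each step from 1 to 6 h, along the axis of the slope and of the contrast of windows. The GAPDH measure ran from -0.009 to 0.101. The upper quartile of the 2 h array was 7.50, against 7.63 to 7.76 in the others. With an estimated correlation no list passed in any comparison, out of 34 lists tested, where camera with its preset correlation had passed 13 for treated against control, 13 at hours 1 to 3, 17 at hours 4 to 7, 13 between the windows and 17 for the slope. Of the 34, 9 passed in no comparison with the preset correlation. These were the interferon-stimulated, BMP and ID, glycolysis, fatty acid synthesis, AHR, apoptosis, extracellular matrix, immune cell and epithelial lists, whose lowest adjusted p values ran from 0.0668 to 0.385.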

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

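The tests of exchanged control labels, a common harvest, RNA quality, stellate cell RNA, cross-hybridisation, medium exchange, normalization and S phase entry were chosen after the results were seen, and those of the 2 h array's distribution and of other groupings before.

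The windows of treated hours differed from each other in 2064 genes. Of the 35 splits of the 7 arrays into 3 and 4, only the real one gave as many, and the highest other count was 0. All other splits mix earlier and later hours, except that of hours 5 to 7 against hours 1 to 4, which also gave 0 genes. The count thus hung on a boundary between 3 and 4 h, which a steady change alone does not account for. A change with time of any cause could lie behind this outcome. It therefore does not tell a response to the supernatant from other change with time. Without the 2 h array 3 genes passed between the windows. The slope over hours gave 3170 genes. Of 100 orders of the hours only the real one gave as many, with 2536 as the highest other, from an order close to the real one. The genes thus followed the hours, as any change with time would make them do, and its cause was not tested by this. For treated against control, 4 of the 45 splits into 8 and 2 gave 6 genes or more, so chance is not excluded there. The highest other split gave 843 genes and set the 24 h treated array and the 0 h control apart from the rest, which points to a structure of the samples other than treatment.

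List medians on opposite sides of the controls' mean in the 2 windows differed as well, tested between the windows with camera. The differences, hours 4 to 7 minus hours 1 to 3, were -0.20 for MAPK feedback genes, -0.052 for EMT and mesenchymal genes, -0.14 for YAP and SRF targets, -0.24 for growth factors and EGFR ligands, -0.64 for ATF4 targets, 1.03 for G1/S genes, 0.25 for ribosome biogenesis and MYC targets, -0.17 for p53 targets and -0.26 for circadian clock genes. None passed with an estimated correlation.

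A sample far from the others was found in 3 of 80 groups tested, which held list medians, measures of array quality and counts of genes, where chance gives about 1 in 20, or 4. The treated 24 h array stood apart in the cholesterol biosynthesis median (gap over range 0.540) and in the G2/M median (0.698), and the 7 h array stood apart from hours 4 to 6 in the epithelial marker median (0.927). Among 3540 probe sets without a single gene symbol, which the main comparisons did not use, 162 were higher and 110 lower at hours 4 to 7 than in the controls.

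The array labelled 24 h control lay near the 1 h treated array, with 63 genes at 2-fold or more between them, and the array labelled 0 h control lay near the 24 h treated array. Degraded RNA is argued against by the ACTB 3-prime measure alone, in which the controls differed by 0.001, where its SD over the arrays was 0.123. The GAPDH measure was 0.046 in the 0 h control and 0.025 in the 24 h control and does not decide it. Exchanged labels of the controls could give the pattern, but the same distances (63 genes, and 388 to the labelled 0 h control) raised that explanation and so do not test it. One harvest for all arrays with supernatant added at staggered times, as a protocol text of the labels words it, could give it too. The series text instead says that cells were harvested hourly, so the sources leave the harvest scheme unclear. The distance from the 24 h control grew at 6 of 7 steps, but these distances also belong to the pattern and so do not test it. Exchanged labels and a common harvest cannot be told apart. Each needs the labelled 24 h control to be the nearer reference for the early arrays, and each control is a single array.

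Metallothionein genes and HMOX1 were higher at hours 1 to 3. RNA of stellate cells carried in the supernatant is argued against only by markers low in the controls. LUM, MGP and POSTN, the lowest there, changed by 0.044, 0.028 and 0.031. The median change of 30 stellate and fibroblast markers was 0.029, none rose by 1 or more and the largest among 8 collagens was 0.58. But several were already high in the controls, such as VIM at 14.6 and COL1A2 at 12.2, where carried RNA could hardly show. Cross-hybridisation among metallothionein copies stays open for those genes, since SLC30A1, at 3.72, was itself among the top genes of the pattern and decides nothing about their probes. Medium exchange without any stellate product may have caused the rise, and it cannot be told apart from a stellate product because no array is labelled as given fresh medium alone. The metallothionein median at 24 h was 0.21 against the 24 h control and 0.70 against the 0 h control, and neither decides it.

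Replication genes were higher at later hours while amino acid response genes fell. The compressed distribution of the 2 h array is argued against as the cause of the G1/S slope. Its median was 0.29 with all 7 arrays (camera adjusted p = 6.99e-21, and adjusted p = 0.253 with an estimated correlation) and 0.268 without that array. The fall of the amino acid response list was not tested in this way. Between the windows only 3 genes passed without the 2 h array, although ORC1 still stood at 2.48 and TRIB3 at -2.01. The authors' normalization stays open. The slope was 0.2699 after cyclic loess, but that scaling was applied on top of the authors' values and so cannot undo their normalization. Cells entering S phase together and reaching mitosis later remains a candidate explanation and no more. The G2/M median was 0.93 higher at 24 h than at 7 h, with 36 of 36 genes higher, while the G1/S median changed by -0.19. This sets 1 array against 1, and the controls, both without supernatant, differed by more than that in the G2/M median. The 24 h treated array lay 0.28 above the 0 h control in that median. A response to the stellate product or to its medium and RNA integrity, whose ACTB measure fell from 1 to 6 h, stay open, untested.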

How the results depend on the processing

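The alternatives that used the 24 h control alone, the 0 h control alone for treated against control, each control alone for lists, cyclic loess for lists, and the 24 h control for each hour were chosen after seeing the data. The cause was not tested for any change below, except that fits without an array or with 1 control had fewer samples and that a size threshold of 0.58 admits smaller differences.

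The 6 genes of treated against control became 16 with the mean of probe sets (5 lower), 15 with every probe set, 36 in the filtered table (9 lower), 2 with a late harvest term, 1 with the 24 h control alone and 1 to 115 without each array in turn. At hours 1 to 3 the 233 became 759 with every probe set, 358 in the filtered table, 1823 with the 0 h control alone, 23 with the 24 h control alone and 23 to 1823 without each array. At hours 4 to 7 the 1636 ran from 740 to 1754 without each array and stayed within 1.5 times otherwise. Between the windows the 2064 became 3572 with every probe set and 3 to 2886 without each array. The slope's 3170 became 932 with the 0 h control as hour 0 and 1611 to 3034 without each array.

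For the 24 h pair the 387 became 682 with every probe set, 1171 at a size of 0.58, 93 against the 0 h control and 111 against the mean of the controls. For the control pair the 276 became 567 with every probe set and 1042 at 0.58. Against the 24 h control in place of the 0 h control, the counts per hour became 63 at 1 h, 143 at 2 h, 176 at 3 h, 245 at 4 h and 387 at 24 h. Lists past the threshold numbered 0 in each of the 5 comparisons with an estimated correlation. With fry they numbered 5 for treated against control, 7 at hours 1 to 3 and 13 at hours 4 to 7. Fry passed 1 between the windows, where cyclic loess left 8, and 18 for the slope.

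Directions reversed as follows. BCL2L11 at hours 1 to 3 was -0.51 in the filtered table. With the 0 h control as hour 0 the slopes of CXCL8 and JUNB were 0.024 and 0.068. Against the 0 h control the 24 h treated array gave 0.57 for KLHDC7B, 0.30 for LAMP3, 0.037 for GDF15, 0.042 for CLGN, 0.039 for BEX2, 0.076 for NUPR1, 0.81 for NIBAN1, 0.11 for ATF4 targets, 0.065 for p53 targets, 0.16 for AHR targets and 0.087 for apoptosis regulators. With the 24 h control alone the G2/M median was 0.20 for treated against control and 0.14 at hours 4 to 7, the immediate-early median at hours 4 to 7 was -0.0054 and the G1/S median at hours 1 to 3 was 0.16. With the 0 h control alone the ATF4 median at hours 4 to 7 was 0.21. Of the genes that the naming rule picked and that passed, 1 of 6 for treated against control, 18 of 48 at hours 1 to 3, 61 of 118 at hours 4 to 7, 2 of 100 between the windows and 94 of 119 for the slope still passed without each array in turn. Where control levels lie near the low end of the arrays, as for MT1M, the background limits the size that can be measured.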
